A study of Mus musculus with 15 samples.

How the data were processed

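RNA sequencing libraries of RAW264.7 cells, a mouse macrophage line transformed by Abelson leukemia virus, were analysed from the deposited gene tables. The 15 libraries fell into 5 groups of 3 by the treatment named in their labels, which were untreated control cells and cells given nonporous Stober silica of nominal size 50 nm (Stober50), nonporous Stober silica of 500 nm (Stober500), mesoporous silica of 500 nm (MSN500) or pegylated mesoporous silica of 500 nm (MSN-PEG500). The dosage labels name an LC50 dose with a value of 13.1 µg/ml for Stober50, 16.8 for Stober500, 111.8 for MSN500 and 84 for MSN-PEG500. Their wording leaves open whether each value is the concentration used or the LC50 it was derived from, and particle and dosage differed together in every comparison. The treatment protocol gives 24 h of exposure and the extraction protocol 4 h, so the exposure time is uncertain. Cells were at passages 6 to 14. The labels give RNA integrity as a range over all samples and name no sequencing lane, day or batch per library, so neither could be compared between groups.

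Per the submitters' processing notes, Novoalign 2.08.03, DESeq2, limma 3.28.21 and the builds GRCm38 and mm10 were used. The authors counted, per the file headers and column descriptions, alignments that overlap a gene by at least 1 base, and the deposited counts are whole numbers that were not normalized. The use of strand in counting is not given in the sources used here, so values of overlapping or antisense genes are uncertain. Every one of the 13342 genes in the deposited count table had at least 10 counts in its highest library. The deposited FPKM values are those counts scaled by exonic length in kb and by the reads of the library, per the column descriptions. They were used only to recover each library's read total, and at most 0.0353% of those reads lay outside the genes of the count table. The authors' deposited log2 ratios come from DESeq2, per the column descriptions, and give the first group named over the second. The deposited score of a gene is -10 log10 of its adjusted p, and the deposited exon score is the same transform of a corrected chi-square p over exons in which replicates were not modelled. Sheets with rlog values, lists past thresholds and gene identifiers were not used here. Count columns were matched to samples through the column name in each sample's description, and 0 columns belonged to other samples.

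Library totals ran from 17683003 to 27253289 counts. At these totals 3 counts, the upper limit that a count of 0 allows, correspond to 0.110 to 0.170 CPM (counts scaled to the library total), a limit that covers counting error only. A chi-square comparison of the replicates within each group, over genes with at least 20 counts in the pair, gave 2.19 to 6.81 per degree of freedom, so no pair differed by as little as sampling noise and none was treated as a duplicate. Gene positions are those of the deposited annotation with the start counted from 1. Of 13173 genes with an identifier in GENCODE M21, an annotation of GRCm38, 99.96% overlapped the annotated gene and 62.5% had the same start and end. Coordinates are therefore given as GRCm38.

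Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 5 groups, which left 12798. TMM factors ranged from 0.974 to 1.02. A quasi-likelihood model of group means was fitted to all 15 libraries with robust estimation (common biological coefficient of variation 0.0418), so that all groups shared an estimate of the spread. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 in the two-sided quasi-likelihood F-test. The 7 comparisons were each particle with control, Stober50 with Stober500, MSN500 with Stober500 and MSN-PEG500 with MSN500, and a further F-test took all 5 groups together. Log2 fold changes are given with their standard error (SE), and CPM values as mean ± SD over 3 libraries, with a prior count of 2 where logarithms were taken. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

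Gene lists for 30 pathways, responses and cell types were fixed before the data were examined, and the 26 with at least 5 measured genes were tested. Camera from limma 3.58.1 compared each list with all other genes on log2 CPM, with a preset correlation between genes of 0.01 and adjustment over the lists within a comparison. Camera was repeated with an estimated correlation. Fry from limma tests whether the genes of a list move on balance one way, or in either direction in its mixed form, and does not compare them with other genes. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. The fibroblast, lymphocyte, epithelial and erythroid and granulocyte lists had 1, 2, 0 and 1 measured members and were not tested.

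The genes named were chosen by a rule fixed before the data were examined. In each comparison with control the rule took the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1, a symbol other than a gene model name and no overlap between the 3 libraries of either group. Comparisons between particles took 5 and 5. Up to 3 members with the smallest adjusted p came from each list with at least 3 called members. The rule always included 16 genes, among them Tnf, Il1b, Il1a, Cxcl2, Ccl2, Hmox1, Nlrp3, Gpnmb, Mt1, Mt2, Msr1, Marco, Cdkn1a and Ddit3, of which Marco was not measured. Genes that the deposited table gives no symbol were passed over. A gene with an empty annotation entry and some genes that the rule takes stayed in library sizes, fits and list counts as they applied and are not reported here.

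The procedure was tested on simulated counts with the means and library sizes of the real samples and 50 genes changed at each of 4 sizes. For MSN500 against control, over 12676 genes, it recovered 68%, 84%, 88% and 100% of genes changed by 0.3, 0.6, 1 and 2 on the log2 scale, with 6 false calls. For Stober500 against control, over 12673 genes, it recovered 66%, 72%, 90% and 100%, with 7 false calls. Of 100 unchanged lists, 2 had a camera p under 0.05 with the preset correlation in either simulation, and a raised list was detected in both. Genes were simulated independently of each other, so these lists could not show whether the preset correlation is too low for the real data.

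Alternatives fixed before the data were examined were RLE size factors as in DESeq2, upper quartile factors, no filter, a stricter filter (CPM of at least 1 in at least 3 libraries and a mean count of at least 10), DESeq2 1.42.0, limma-voom, the replicate number as a block, a model of only the groups compared, a stricter threshold (adjusted p under 0.01 and an absolute log2 change of at least 1) and leaving out each library in turn. Removal of a gene length and GC content trend from each library (natural splines with 4 degrees of freedom, as an offset, with GC content for 98.7% of genes), camera on MSN500 against Stober50 and list tests without each single library were added after seeing the data. An adjusted p that DESeq2 did not give was left missing. Effects against the same controls were set beside 20 simulations of unchanged groups that shared those controls. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.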

Results

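Gene expression in RAW264.7 mouse macrophages was measured by sequencing of 15 RNA libraries, 3 from untreated control cells and 3 from each of 4 silica nanoparticle treatments. The series set out to compare how nonporous and porous silica particles change macrophage gene expression. Library totals ranged over the 3 libraries of each group from 19331632 to 23263294 counts in control, 24756303 to 27253289 in Stober50, 19670973 to 26715096 in Stober500, 19216971 to 23181412 in MSN500 and 17683003 to 22554806 in MSN-PEG500. Of 12798 genes tested, 6364 (49.7%) differed among the 5 groups at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which is the test behind every adjusted p of a single gene. Mitochondrially encoded genes took 1.33% to 1.70% of the counts of a library. Few markers of other cell types passed the filter on low counts, with Pdgfrb the only fibroblast marker (highest library 1.82 CPM), S100a8 the only erythroid or granulocyte marker (1.40 CPM) and no epithelial marker. Lck and Ighm were the lymphocyte markers that passed it, with a highest value of 10.2 CPM.

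The first principal component of log2 CPM carried 49.6% of the variance and separated the libraries of both mesoporous particles from the other 9. The second component carried 7.47%, and MSN-PEG500 replicate 3 stood apart from the other MSN-PEG500 libraries along it, at -19.1 against -4.85 and -3.48.

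**Figure D1:**
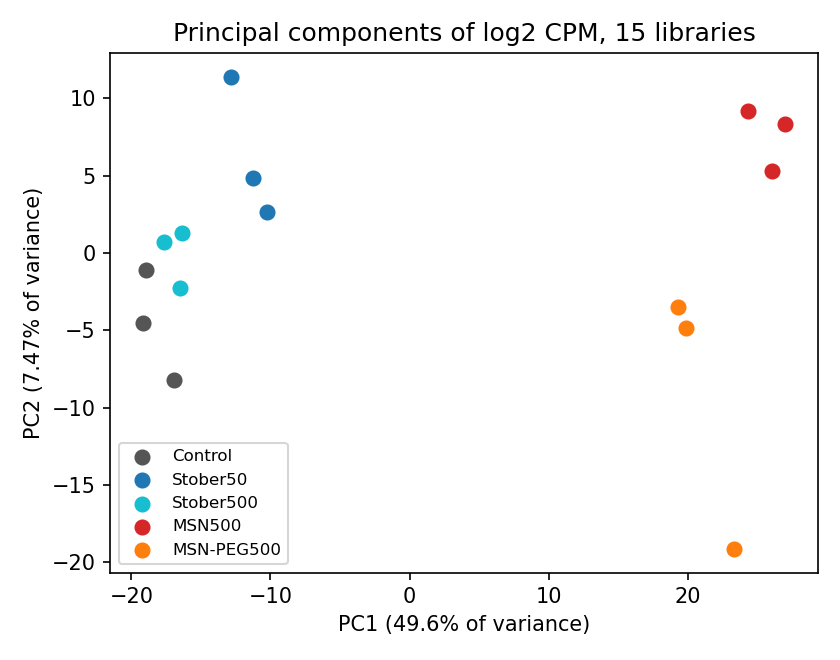
Scores of the 15 libraries on the first and second principal components of log2 CPM, in arbitrary units, with 1 point per library coloured by group. The 6 mesoporous particle libraries lie between 19.3 and 27.0 on the first component, and the 9 control and Stober libraries between -19.2 and -10.2.

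Stober50 was compared with control to find the response to the smaller nonporous particle. Genes of cholesterol synthesis and uptake were lower and genes of lysosomes and autophagy higher in treated cells. Cyp51, a sterol demethylase of the cholesterol pathway, was at 81.4 ± 1.81 CPM in Stober50 and 113 ± 3.91 in control (SD, n = 3 each), a log2 change of -0.47 ± 0.05 (SE, adjusted p = 1.32e-06). Hal, which encodes histidine ammonia-lyase, showed the largest rise under the naming rule, from 9.0 ± 0.127 to 22.1 ± 3.12 CPM (log2 change 1.30 ± 0.12, adjusted p = 1.43e-06). Sqstm1, the autophagy receptor p62, rose from 400 ± 9.70 to 536 ± 5.22 CPM (log2 change 0.42 ± 0.04). Hmox1, the heme-degrading enzyme, rose by 0.46 ± 0.05 on the log2 scale from 132 ± 5.40 to 181 ± 6.42 CPM.

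In all, 493 genes rose and 476 fell with Stober50, 16 of these 969 by at least 2-fold. The share that rose, 50.9%, was 66.0% without Stober50 replicate 1, 68.9% without Stober50 replicate 2, 64.9% without control replicate 3 and 62.4% with a length and GC content trend removed, a setting chosen after seeing the data in which 661 of the 969 genes were still called. Bcar3 rose by 0.93 ± 0.09 and the chemokine receptor gene Cxcr4 by 0.85 ± 0.07, from 40.7 ± 0.955 to 73.6 ± 5.27 CPM. Angptl2, whose counts can include reads of the overlapping Ralgps1 on the opposite strand, had a log2 change of 1.12 ± 0.17. Malat1, a nuclear long noncoding RNA, fell by 0.82 ± 0.10 on the log2 scale, from 520 ± 32.7 to 295 ± 35.1 CPM. Bmf, a proapoptotic BH3-only gene, fell by 0.61 ± 0.12 and Trp53inp1 fell by 0.58 ± 0.12. The cytokine genes Tnf (log2 change 0.49 ± 0.19, adjusted p = 0.166), Cxcl2 (0.30 ± 0.23, adjusted p = 0.495) and Il1b (0.09 ± 0.21, adjusted p = 0.848) did not pass. Hal lies on chromosome 10 at 93488768 to 93519304 on the plus strand (GRCm38, ENSMUSG00000020017), and Cyp51 on chromosome 5 at 4081145 to 4104746 on the minus strand (ENSMUSG00000001467), both protein-coding.

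Of 26 measured genes for cholesterol synthesis and uptake, 20 fell with Stober50, 0 rose and 6 did not pass (22 fell adjusted over the list alone). Cyp51 and Stard4, a sterol transport gene, were among those that fell, Stard4 with a log2 change of -0.36 ± 0.04. Camera from limma placed the list below other genes (adjusted p = 8.49e-21, and adjusted p = 0.0128 with an estimated correlation). Of 44 lysosome and autophagy genes, 21 rose and 0 fell (29 rose adjusted over the list alone), among them the protease gene Ctsb (0.26 ± 0.04) and the galactosidase gene Gla (0.34 ± 0.05), with a camera adjusted p = 4.24e-17 and adjusted p = 0.0326 with an estimated correlation. That second call was lost without Stober50 replicate 3 (adjusted p = 0.0748 with an estimated correlation), control replicate 1 (0.0690) or control replicate 3 (0.0547). Replication-dependent histone genes, whose level can depend on RNA selection, had a list mean of -0.25 ± 0.0410 relative to control in Stober50 (SD, n = 3; control SD 0.0671), with 0 of 7 genes past the threshold and a camera adjusted p = 0.270. Of 23 antioxidant genes controlled by NRF2, 5 rose and 0 fell (9 rose adjusted over the list alone), including the ferritin genes Fth1 (0.24 ± 0.04) and Ftl1 (0.28 ± 0.04), whose counts overlap those of Gm22133. That list had a camera adjusted p = 2.84e-05 and adjusted p = 0.102 with an estimated correlation. Among 14 LXR targets, which include lipid efflux genes, Abcg1 rose by 0.54 ± 0.08 and Abca1 by 0.35 ± 0.07 while the fatty acid synthase gene Fasn fell by 0.25 ± 0.05, and the list of 5 that rose and 1 that fell (7 and 2 adjusted over the list alone) had a camera adjusted p = 0.0801 (0.0336 without control replicate 2).

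The list of 33 NF-kB cytokines and chemokines had 4 genes that rose and 0 that fell (5 and 1 adjusted over the list alone), including Ccl7 (0.67 ± 0.15, adjusted p = 0.00732), with a camera adjusted p = 0.00205 and adjusted p = 0.473 with an estimated correlation. That call rested on Stober50 replicate 3, without which the list mean moved from 0.19 to 0.07 and the camera adjusted p was 0.357. Of 21 p53 targets, 5 fell and 0 rose (8 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00199). Its adjusted p = 0.0804 with an estimated correlation (0.0453 without control replicate 2). Actin and adhesion genes rose in 6 of 27 cases (8 adjusted over the list alone; camera adjusted p = 0.00392, adjusted p = 0.391 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose in 2 of 35 cases (4 adjusted over the list alone), with a camera adjusted p = 2.14e-04 and adjusted p = 0.391 with an estimated correlation. Log2 changes in this comparison were related to exonic length across genes, which are not independent replicates, with Spearman's rho -0.263, so short genes tended to be higher in Stober50. Their rho with GC content was 0.230, and 0.103 without control replicate 1. The count of 969 changed genes depended on single libraries, falling to 533 without Stober50 replicate 1, 412 without Stober50 replicate 2, 584 without control replicate 1 and 631 without control replicate 2.

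Stober500 was compared with control to find the response to the larger nonporous particle. Snhg17, a small nucleolar RNA host gene, was the only gene called, at 37.8 ± 1.45 CPM against 49.5 ± 2.41 in control (SD, n = 3 each; log2 change -0.39 ± 0.06, adjusted p = 0.00368, and adjusted p = 0.0562 without Stober500 replicate 1). It is annotated as a processed transcript on chromosome 2 at 158355307 to 158361580 on the minus strand (GRCm38, ENSMUSG00000085385) and holds small genes whose reads can be counted with it. Hmox1 was at 146 ± 13.3 CPM against 132 ± 5.40 (log2 change 0.15 ± 0.05, adjusted p = 0.231, and adjusted p = 0.0214 without Stober500 replicate 3) and Tnf was at 62.4 ± 4.77 CPM against 64.0 ± 10.2 (log2 change -0.04 ± 0.20, adjusted p = 0.966).

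Between Stober500 and control, 1526 of 12798 genes had an unadjusted p under 0.05, a threshold that a share of 0.05 of unchanged genes would pass. DESeq2 called 91 genes and limma-voom 4. With edgeR the count moved to 0 without Stober500 replicate 1, 2 without Stober500 replicate 2, 90 without Stober500 replicate 3, 6 without control replicate 1, 2 without control replicate 2 and 2 without control replicate 3. DESeq2 gave Snhg17 no adjusted p. No member of any list passed over all genes tested. Camera from limma placed lysosome and autophagy genes (median log2 change 0.06 over 44 genes, 37 of them higher) and nuclear genes of oxidative phosphorylation (0.05 over 35, 32 higher; 3 rose adjusted over the list alone) above other genes, each at an adjusted p = 1.66e-05 and an adjusted p = 0.617 with an estimated correlation. Genes of glycolysis and hypoxia (0.13 over 31 genes, 27 higher) had an adjusted p = 3.71e-04 and adjusted p = 0.893 with an estimated correlation. DNA replication genes lay lower (median -0.03, 5 of 31 fell adjusted over the list alone, camera adjusted p = 0.00357, adjusted p = 0.617 with an estimated correlation). Interferon response genes (median -0.10, adjusted p = 0.00623) and mitosis genes (median -0.05, adjusted p = 0.00754) also lay lower, with an adjusted p = 0.986 and an adjusted p = 0.968 with an estimated correlation. Scavenger receptor genes (2 of 29 rose adjusted over the list alone) and NRF2 genes (0 of 23) lay higher, each at a camera adjusted p = 0.0205 and an adjusted p = 0.617 with an estimated correlation. Of these 8 lists, 6 lost the camera call without a single library. Interferon response genes lost it without Stober500 replicate 1 (adjusted p = 0.287), Stober500 replicate 2 (0.384) or control replicate 1 (0.157), and mitosis genes without the same libraries (0.149, 0.529 and 0.199). Glycolysis genes lost it without Stober500 replicate 2 (0.121) or control replicate 1 (0.112), DNA replication genes without Stober500 replicate 2 (0.0753) and NRF2 genes without Stober500 replicate 2 (0.0753) or control replicate 2 (0.0771). Scavenger receptor genes lost it without Stober500 replicate 2 (0.121), Stober500 replicate 3 (0.0808) or control replicate 1 (0.199). Without Stober500 replicate 3 the list mean moved from -0.10 to -0.20 for interferon response, from -0.04 to -0.08 for mitosis and from 0.13 to 0.23 for glycolysis genes. Across genes, log2 changes were related to exonic length with rho -0.257, short genes tending to be higher in Stober500. Stober50 had rho -0.263 against the same control libraries, and rho between the Stober particles was -0.0771. The relation therefore cannot be assigned to the particles rather than to the shared controls. For Stober500 against control, rho with GC content was 0.0182 with all libraries. Without single libraries it lay between -0.132 (without control replicate 1) and 0.162 (without Stober500 replicate 3). The cholesterol list had a median log2 change of 0.01 and a camera adjusted p = 0.651.

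MSN500 was compared with control to find the response to the mesoporous particle. Lysosome, cholesterol and metal transport genes were higher in treated cells. Fabp4, which encodes a fatty acid binding protein, was at 11.3 ± 1.22 CPM in MSN500 and 0.501 ± 0.0778 in control (SD, n = 3 each), 22.6-fold higher (log2 change 4.50 ± 0.18, adjusted p = 4.44e-17). Atp6v0d2, a subunit of the proton pump of lysosomes and osteoclasts, rose 12.8-fold from 2.02 ± 0.177 to 25.8 ± 1.87 CPM. Gpnmb, a glycoprotein of lysosomes, rose from 2781 ± 88.0 to 9018 ± 243 CPM (log2 change 1.70 ± 0.06). Tgfbi, a matrix protein gene induced by TGF-beta, fell from 11.6 ± 0.403 to 1.19 ± 0.299 CPM and was 9.69-fold higher in control (adjusted p = 5.52e-16).

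With MSN500, 2770 genes rose and 2719 fell, and 444 of these 5489 changed by at least 2-fold. With upper quartile factors 43.9% of the changed genes were rises. Il7r, the interleukin 7 receptor gene, rose by 3.40 ± 0.18, the terminal nucleotidyltransferase gene Fam46c by 3.08 ± 0.13 and Hal by 3.03 ± 0.10. Akap2 and Pakap, overlapping gene models with nearly the same reads (count ratio 0.999), both rose by 4.24 ± 0.19 and cannot be told apart. Log2 changes were -2.65 ± 0.15 for Bmf, -2.42 ± 0.15 for Nt5e, a gene of the ecto-nucleotidase CD73, -1.67 ± 0.09 for the caveolin gene Cav1 and -1.56 ± 0.09 for Pdcd4, which overlaps Bbip1 on the opposite strand. Xirp1, which overlaps the far more abundant Cx3cr1, had a log2 change of -1.85 ± 0.20. Fabp4 lies on chromosome 3 at 10204347 to 10208576 on the minus strand (ENSMUSG00000062515), Tgfbi on chromosome 13 at 56609603 to 56639339 on the plus strand (ENSMUSG00000035493), Atp6v0d2 on chromosome 4 at 19876841 to 19922605 on the minus strand (ENSMUSG00000028238) and Gpnmb on chromosome 6 at 49036518 to 49058182 on the plus strand (ENSMUSG00000029816), all protein-coding genes of GRCm38.

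**Figure D2:**
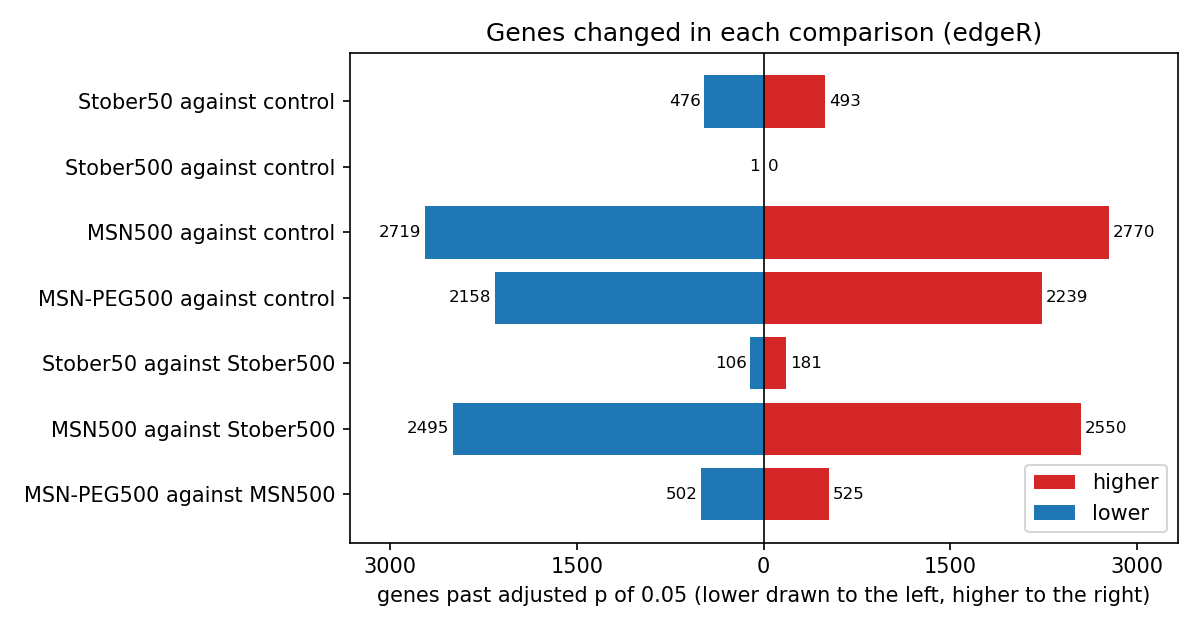
Number of genes changed in each of the 7 comparisons at an adjusted p under 0.05 in edgeR's quasi-likelihood test, with bars for genes higher and genes lower in the first group named. MSN500 and MSN-PEG500 changed 5489 and 4397 genes against control, Stober50 969 and Stober500 1.

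Of 44 lysosome and autophagy genes, 40 rose with MSN500, 3 fell and 1 did not pass, with the same counts adjusted over the list alone. Ctsd, which encodes the lysosomal protease cathepsin D, rose from 2297 ± 15.3 to 4871 ± 34.5 CPM (log2 change 1.08 ± 0.04), and Sqstm1 rose by 1.03 ± 0.04. Camera gave this list an adjusted p = 6.61e-21 and an adjusted p = 0.0206 with an estimated correlation. Of 26 cholesterol genes, 23 rose and 0 fell (the same adjusted over the list alone), the direction opposite to that with Stober50. Lss, the lanosterol synthase gene, rose by 0.99 ± 0.04 from 67.1 ± 1.92 to 133 ± 5.35 CPM, and Cyp51 by 1.07 ± 0.05. The list had a camera adjusted p = 2.68e-15 and adjusted p = 0.0206 with an estimated correlation. Of 10 metallothionein and metal transport genes, 6 rose and 0 fell (7 rose adjusted over the list alone; camera adjusted p = 0.00154, adjusted p = 0.0415 with an estimated correlation). Leaving out any 1 of the 6 libraries ended the second of these calls (with the highest adjusted p = 0.0790, without control replicate 3). These included Slc40a1, the iron exporter ferroportin (1.78 ± 0.15), Slc11a2, an iron importer (0.86 ± 0.04), Mt2 (1.15 ± 0.09) and Mt1 (0.73 ± 0.06). Of 21 endoplasmic reticulum (ER) chaperone and unfolded protein response genes, 19 rose and 1 fell, with the same counts adjusted over the list alone, among them Creld2 (0.74 ± 0.05) and Manf (0.62 ± 0.05). That list had a camera adjusted p = 2.96e-09 and an adjusted p = 0.0764 with an estimated correlation. The histone list mean was -0.15 ± 0.0615 in MSN500 (SD, n = 3; camera adjusted p = 0.993).

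Of 33 NF-kB cytokines and chemokines, 21 rose with MSN500 and 2 fell (23 and 2 adjusted over the list alone; camera adjusted p = 1.02e-05, adjusted p = 0.381 with an estimated correlation). Tnf rose from 64.0 ± 10.2 to 159 ± 10.7 CPM (log2 change 1.31 ± 0.19, adjusted p = 1.90e-04) and the neutrophil chemokine gene Cxcl2 by 1.25 ± 0.23 (adjusted p = 0.00122). Il1a had a log2 change of 0.90 ± 0.33 (adjusted p = 0.0438) that missed the threshold with upper quartile factors (adjusted p = 0.0501) and without control replicate 1 (0.149), control replicate 2 (0.0669), MSN500 replicate 2 (0.109) or MSN500 replicate 3 (0.120). Il1b had -0.66 ± 0.23 (adjusted p = 0.0393) and missed it with limma-voom (adjusted p = 0.0511) and without control replicate 2 (0.132), control replicate 3 (0.117), MSN500 replicate 1 (0.115) or MSN500 replicate 3 (0.0813). Ccl2 did not pass (0.21 ± 0.16, adjusted p = 0.324). Of 16 inflammasome genes, 10 fell, among them P2rx7, an ATP-gated channel gene (-0.48 ± 0.04), and Il18 (-0.68 ± 0.08), and 3 rose, among them the interleukin 1 receptor antagonist gene Il1rn (2.03 ± 0.09), with the same counts adjusted over the list alone. The list had a camera adjusted p = 0.0388 and adjusted p = 0.381 with an estimated correlation. Of 23 NRF2 genes, 13 rose and 3 fell (14 and 3 adjusted over the list alone), led by Hmox1 (1.28 ± 0.05) and Fth1 (0.84 ± 0.04), with a camera adjusted p = 8.18e-04 and adjusted p = 0.218 with an estimated correlation. Of 30 mitosis genes, 20 fell and 0 rose, as many as adjusted over the list alone, for example the checkpoint kinase gene Bub1b (-0.40 ± 0.04), with a camera adjusted p = 2.20e-06 and adjusted p = 0.381 with an estimated correlation. Of 45 interferon response genes, 17 fell and 2 rose over all genes and adjusted over the list alone (camera adjusted p = 0.00454, adjusted p = 0.720 with an estimated correlation), with a list mean of -0.21 that was -0.14 without MSN500 replicate 2. Across genes, log2 changes with MSN500 were related to exonic length with rho -0.111.

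**Figure D3:**
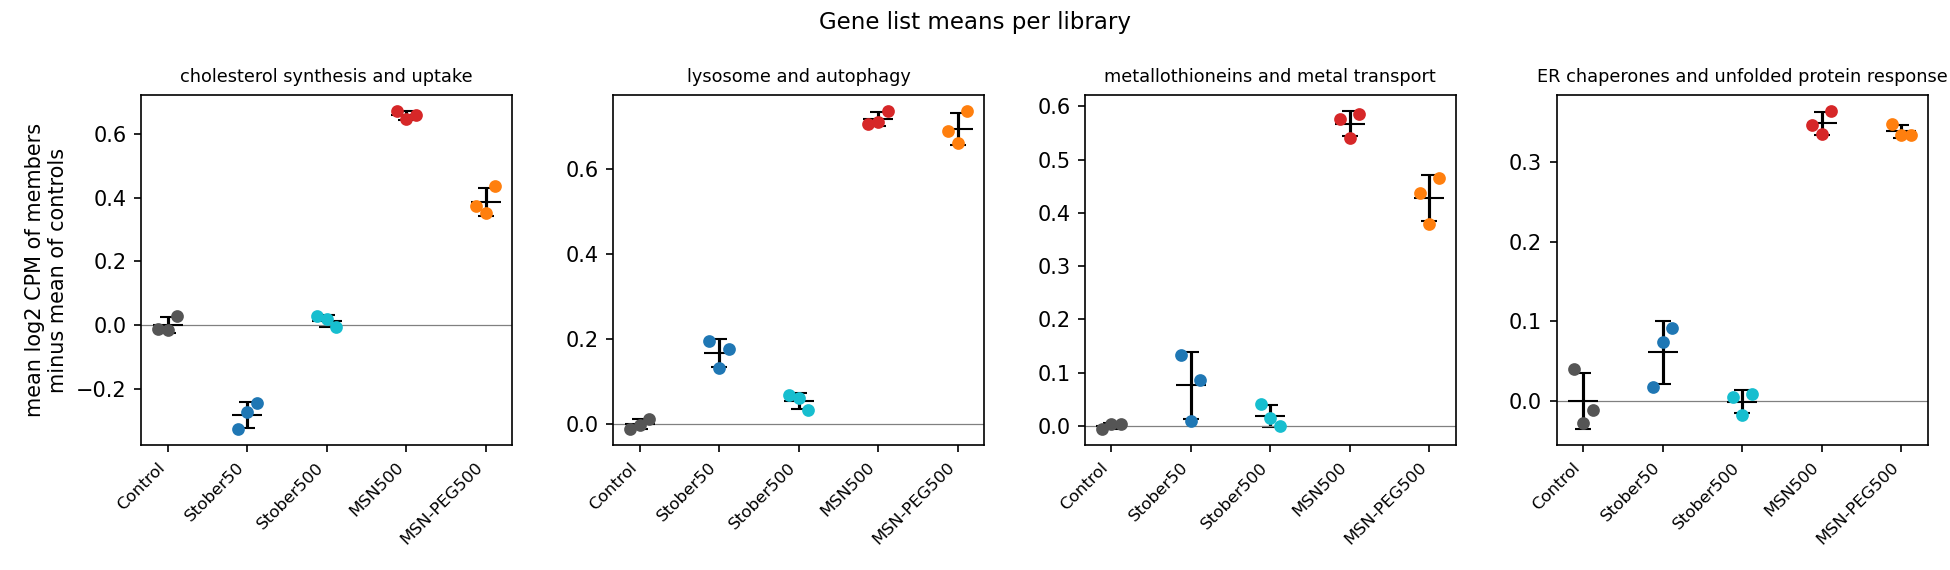
Mean log2 difference from the control mean for each library, averaged over the genes of selected lists, with points for the 3 libraries of each group and bars for mean ± SD (n = 3); panels have their own vertical scales. The cholesterol list lay at -0.28 ± 0.0411 in Stober50, 0.01 ± 0.0186 in Stober500, 0.66 ± 0.0134 in MSN500 and 0.39 ± 0.0439 in MSN-PEG500.

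MSN-PEG500 was compared with control to find the response to the pegylated mesoporous particle. Lysosome, cholesterol, metal transport and ER chaperone genes were higher in treated cells. Fabp4 rose 16.5-fold, from 0.501 ± 0.0778 to 8.27 ± 0.959 CPM (SD, n = 3 each; log2 change 4.04 ± 0.19, adjusted p = 1.93e-15), and Atp6v0d2 12.2-fold to 24.6 ± 4.86 CPM. Gpnmb rose by 1.62 ± 0.06 to 8563 ± 214 CPM, and Hmox1 by 1.26 ± 0.05 to 314 ± 11.1 CPM. Tgfbi fell by 2.55 ± 0.13 on the log2 scale, to 1.94 ± 0.513 CPM.

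With MSN-PEG500, 2239 genes rose and 2158 fell, 339 of these 4397 by at least 2-fold. Rises made up 40.9% of the changed genes with upper quartile factors and 45.2% with the length and GC content trend removed. Over 141 genes with a deposited exon score of at least 20, the exon log2 ratio of control over MSN-PEG500 had Spearman's rho -0.201 with exon position. A difference in RNA integrity or end bias may therefore also enter this comparison, and its part in the changed genes was not tested. Log2 changes had rho -0.0966 with GC content across genes. It was 0.0224 without MSN-PEG500 replicate 3 and -0.155 without control replicate 1. Il7r rose by 3.44 ± 0.18, Hal by 3.23 ± 0.10 and Fam46c by 3.15 ± 0.13. Among genes that fell were Bmf (-2.04 ± 0.14), Nt5e (-1.79 ± 0.14), Cav1 (-1.33 ± 0.09) and Ahrr, the repressor of the aryl hydrocarbon receptor (-1.30 ± 0.07). Tnf rose by 1.03 ± 0.19 (adjusted p = 0.00153) and Cxcl2 by 1.12 ± 0.23 (adjusted p = 0.00329), while Il1b had a log2 change of -0.49 ± 0.23 (adjusted p = 0.132, and adjusted p = 0.0350 without control replicate 1). Msr1, a scavenger receptor gene that binds silica, was at a log2 change of -0.06 ± 0.04 (adjusted p = 0.246).

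Of 44 lysosome and autophagy genes, 38 rose with MSN-PEG500 and 0 fell (40 and 1 adjusted over the list alone; camera adjusted p = 7.82e-26, adjusted p = 0.0144 with an estimated correlation), among them Gla (1.29 ± 0.05) and Sqstm1 (0.98 ± 0.04). Of 26 cholesterol genes, 18 rose and 0 fell (22 rose adjusted over the list alone; camera adjusted p = 2.43e-11, adjusted p = 0.0386 with an estimated correlation), including Cyp51 (0.70 ± 0.05), Fdps (0.65 ± 0.05) and Lss (0.60 ± 0.04). Of 21 ER chaperone genes, 18 rose and 0 fell (20 rose adjusted over the list alone; camera adjusted p = 2.43e-11, adjusted p = 0.0424 with an estimated correlation), and of 10 metal genes 7 rose and 0 fell over all genes and adjusted over the list alone (camera adjusted p = 0.00102, adjusted p = 0.0386 with an estimated correlation). With an estimated correlation these calls depended on single libraries. The cholesterol list missed the threshold without control replicate 1 (adjusted p = 0.0556), control replicate 3 (0.0545), MSN-PEG500 replicate 1 (0.0569) or MSN-PEG500 replicate 2 (0.0526). The ER chaperone list missed it without the same libraries (0.0503, 0.0545, 0.0569 and 0.0645) or MSN-PEG500 replicate 3 (0.0865), and so did the metal list (0.0556, 0.0545, 0.0569, 0.0526 and 0.0690). Of 45 interferon response genes, 26 fell, including Irf9 (-0.32 ± 0.05), which overlaps Rnf31, and Oasl1 (-0.43 ± 0.07), and 1 rose, counts unchanged adjusted over the list alone (camera adjusted p = 1.05e-05, adjusted p = 0.447 with an estimated correlation). Of 33 NF-kB genes, 16 rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 3.26e-05, adjusted p = 0.397 with an estimated correlation). Of 30 mitosis genes, 21 fell and 0 rose (22 fell adjusted over the list alone; camera adjusted p = 8.55e-07, adjusted p = 0.381 with an estimated correlation). Of 22 matrix protease and remodelling genes, 14 rose and 3 fell over all genes and adjusted over the list alone, the growth factor genes Pdgfb (0.85 ± 0.06) and Igf1 (0.44 ± 0.04) among those that rose (camera adjusted p = 7.06e-04, adjusted p = 0.115 with an estimated correlation).

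Stober50 was compared with Stober500 to set the smaller against the larger nonporous particle, at dosage labels of 13.1 and 16.8 µg/ml. Cholesterol genes were lower in Stober50. Cyp51 was at 81.4 ± 1.81 CPM in Stober50 and 119 ± 1.29 in Stober500 (SD, n = 3 each; log2 change -0.55 ± 0.05, adjusted p = 2.41e-07), and the squalene epoxidase gene Sqle had a log2 change of -0.39 ± 0.04. Slc6a8, a creatine transporter gene, was higher in Stober50, at 89.7 ± 3.96 against 53.7 ± 2.96 CPM (log2 change 0.74 ± 0.06), as were Hal (0.93 ± 0.11) and the lipid efflux genes Abcg1 (0.62 ± 0.08) and Abca1 (0.38 ± 0.07).

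In this comparison 181 genes were higher and 106 lower in Stober50, 0 of these 287 by at least 2-fold. Of 26 cholesterol genes, 19 were lower and 0 higher (22 and 1 adjusted over the list alone; camera adjusted p = 9.29e-30, adjusted p = 0.00313 with an estimated correlation). Of 44 lysosome and autophagy genes, 9 were higher and 0 lower (18 and 1 adjusted over the list alone; camera adjusted p = 1.11e-10, adjusted p = 0.137 with an estimated correlation). Of 45 interferon response genes, 5 were higher, including Usp18 (0.43 ± 0.09), and 0 lower (6 higher adjusted over the list alone; camera adjusted p = 9.83e-07, adjusted p = 0.420 with an estimated correlation), with a list mean difference of 0.18 that was 0.27 without Stober50 replicate 1 and 0.28 without Stober500 replicate 3. The call of Usp18 missed the threshold without Stober50 replicate 2 (adjusted p = 0.0918), Stober50 replicate 3 (0.0828), Stober500 replicate 1 (0.0952) or Stober500 replicate 2 (0.101). Hmox1 was higher in Stober50 (0.31 ± 0.05), and Tnf did not pass (0.52 ± 0.19, adjusted p = 0.245). The count of 287 moved to 158 without Stober50 replicate 2, 186 without Stober50 replicate 3, 176 without Stober500 replicate 1 and 144 without Stober500 replicate 2. Across genes, log2 changes were related to GC content with rho 0.274 (0.0982 without Stober500 replicate 3) and to exonic length with rho -0.0771 (-0.0187 without Stober50 replicate 2, -0.116 without Stober500 replicate 2 and -0.0364 without Stober500 replicate 3). The histone list mean was -0.25 ± 0.0410 in Stober50 and -0.06 ± 0.176 in Stober500 relative to control (SD, n = 3; camera adjusted p = 0.150).

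MSN500 was compared with Stober500 to set a porous against a nonporous particle of the same nominal size, at dosage labels of 111.8 and 16.8 µg/ml. Fabp4 was 18.0-fold higher in MSN500, at 11.3 ± 1.22 against 0.638 ± 0.103 CPM (SD, n = 3 each; log2 difference 4.17 ± 0.17, adjusted p = 5.83e-17), and Atp6v0d2 10.4-fold higher. Gpnmb was higher by 1.60 ± 0.06, Hmox1 by 1.13 ± 0.05, Tnf by 1.35 ± 0.19 and Cxcl2 by 1.35 ± 0.23. Tgfbi (-3.31 ± 0.14), Bmf (-2.68 ± 0.15) and Nt5e (-2.37 ± 0.15) were lower.

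Between these particles 2550 genes were higher and 2495 lower in MSN500, 401 of the 5045 by at least 2-fold. With upper quartile factors 42.3% of the changed genes were higher in MSN500. Lysosome genes were higher in 40 and lower in 3 of 44 cases (40 and 4 adjusted over the list alone; camera adjusted p = 2.60e-20, adjusted p = 0.0172 with an estimated correlation), and cholesterol genes higher in 24 and lower in 0 of 26 over all genes and adjusted over the list alone (camera adjusted p = 1.31e-16, adjusted p = 0.0172 with an estimated correlation). Of 10 metal genes 8 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 3.95e-04, adjusted p = 0.0219 with an estimated correlation, and 0.0519 without Stober500 replicate 3). ER chaperone genes were higher in 19 and lower in 1 of 21 cases (20 and 1 adjusted over the list alone; camera adjusted p = 6.24e-10, adjusted p = 0.0627 with an estimated correlation). NF-kB genes were higher in 22 and lower in 2 of 33 cases (23 and 2 adjusted over the list alone; camera adjusted p = 1.93e-06, adjusted p = 0.389 with an estimated correlation), and mitosis genes lower in 20 and higher in 0 of 30 cases over all genes and adjusted over the list alone (camera adjusted p = 3.37e-05, adjusted p = 0.472 with an estimated correlation).

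MSN-PEG500 was compared with MSN500 to find the effect of pegylation among mesoporous particles, at dosage labels of 84 and 111.8 µg/ml. Cholesterol synthesis genes were lower in MSN-PEG500. Abca1, the cholesterol efflux transporter gene, was at 66.8 ± 1.79 CPM in MSN-PEG500 and 37.5 ± 2.51 in MSN500 (SD, n = 3 each; log2 difference 0.83 ± 0.08, adjusted p = 1.44e-06), and Abcg1 was higher by 0.64 ± 0.09. Mvd, an enzyme of the mevalonate pathway whose counts can include reads of the overlapping Gm20388, was at 69.5 ± 1.52 against 97.6 ± 4.12 CPM (-0.49 ± 0.05), and Lss had a log2 difference of -0.38 ± 0.04. Olr1, an oxidized lipoprotein receptor gene, was higher by 1.07 ± 0.14, and the transcription factor gene Cebpb, which overlaps Tmem189 on the opposite strand, lower (-0.71 ± 0.12). Abca1 lies on chromosome 4 at 53030787 to 53159895 on the minus strand of GRCm38 (ENSMUSG00000015243).

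Between the mesoporous particles 525 genes were higher and 502 lower in MSN-PEG500, 11 of the 1027 by at least 2-fold. With a length and GC content trend removed, a setting chosen after seeing the data, 368 were higher and 641 lower (36.5% higher in place of 51.1%), and 650 of the 1027 genes were still called. Of 26 cholesterol genes, 21 were lower and 0 higher (22 lower adjusted over the list alone; camera adjusted p = 4.44e-19, adjusted p = 0.0176 with an estimated correlation, which was 0.0525 without MSN-PEG500 replicate 1 and 0.0571 without MSN-PEG500 replicate 2). Of 35 nuclear oxidative phosphorylation genes, 11 were lower and 0 higher (16 lower adjusted over the list alone), for example Cox5a (-0.22 ± 0.04) and Cox8a (-0.24 ± 0.05), with a camera adjusted p = 3.76e-08 and adjusted p = 0.283 with an estimated correlation. Log2 differences in this comparison were related to exonic length across genes with rho 0.267 and to GC content with rho -0.219 (-0.0262 without MSN-PEG500 replicate 3), so short genes tended to be lower in MSN-PEG500. The histone list mean was 0.07 ± 0.123 in MSN-PEG500 and -0.15 ± 0.0615 in MSN500 relative to control (SD, n = 3; camera adjusted p = 0.0867, and adjusted p = 0.0477 without MSN500 replicate 2 and 0.0455 without MSN-PEG500 replicate 1). Of 27 ATF4 stress response genes, 6 were lower and 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 6.91e-04, adjusted p = 0.283 with an estimated correlation), with a list mean difference of -0.12 that was -0.08 without MSN-PEG500 replicate 3. LXR targets were higher in 3 and lower in 0 of 14 cases (4 higher adjusted over the list alone; camera adjusted p = 0.0438, adjusted p = 0.443 with an estimated correlation, and camera adjusted p = 0.0959 without MSN-PEG500 replicate 2). Lysosome genes were higher in 1 and lower in 4 of 44 cases (1 and 5 adjusted over the list alone; camera adjusted p = 0.242, and 0.0443 without MSN-PEG500 replicate 3), and Gpnmb (-0.07 ± 0.05, adjusted p = 0.448), Hmox1 (-0.02 ± 0.05, adjusted p = 0.832) and Tnf (-0.29 ± 0.18, adjusted p = 0.393) did not pass. The count of 1027 moved to 420 without MSN500 replicate 1, 651 without MSN500 replicate 2, 606 without MSN500 replicate 3 and 615 without MSN-PEG500 replicate 3.

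Across the 7 comparisons, 70 of 182 tests of a list passed with the preset correlation and 14 with an estimated correlation. Those 14 were the cholesterol list in every comparison except Stober500 with control, the lysosome list in the Stober50, MSN500 and MSN-PEG500 comparisons with control and in MSN500 with Stober500, the metal list in both mesoporous comparisons with control and in MSN500 with Stober500, and the ER chaperone list in MSN-PEG500 with control. Leaving single libraries out of the list tests, a check chosen after seeing the data, ended 21 of the 70 calls and 7 of the 14 for at least 1 library of the groups compared. In the authors' deposited table, with a score of at least 20 and an absolute log2 ratio of at least 1, the comparisons with control held 192 genes for MSN500, 136 for MSN-PEG500, 1 for Stober50 and 0 for Stober500, and the comparison of MSN-PEG500 with MSN500 held 0. At that score alone the authors' deposited table held 3962 genes for MSN500, 3081 for MSN-PEG500, 521 for Stober50 and 17 for Stober500 against control, and 520 for MSN-PEG500 against MSN500.

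The effects of pairs of particles against control were compared over all 12798 genes, which are not independent replicates. Log2 changes with MSN500 and MSN-PEG500 had Pearson's r = 0.883, where unchanged groups sharing the same control libraries gave a simulated r of 0.483, and their covariance exceeded the simulated covariance by 0.147. Both particles raised 1906 genes and lowered 1682, where independent lists would share 485 and 458, and 6 genes went in opposite directions where independent lists would give 943. Stober50 and MSN500 had r = 0.529 against a simulated 0.517 and a covariance difference of 0.0364, with 415 genes raised by both (107 for independent lists), 355 lowered by both (101.1) and 49 opposite (208). Stober50 and MSN-PEG500 had r = 0.492 against 0.505 and a covariance difference of 0.0291, with 364 genes raised by both (86.3 for independent lists) and 246 lowered by both (80.3). Stober500 had r = 0.562 with Stober50, 0.301 with MSN500 and 0.293 with MSN-PEG500, against simulated values of 0.525, 0.504 and 0.496, and covariance differences of 0.00838, 0.0117 and 0.00910. The 3 control libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls. The simulated counts held no length or GC content trend, so such a trend in the control libraries would not be corrected for.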

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

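The comparison of MSN500 with Stober50, the test of a response that grows with dosage, the dosage ratio, the removal of the length and GC content trend, the test without MSN-PEG500 replicate 3 and the comparison of lysosome list means were chosen only after the results were seen. So were the comparisons of replicate pairs, of library totals, of oxidative phosphorylation list means and of GC content relations without single libraries.

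The effects of 2 particles on genes of cholesterol synthesis and uptake had opposite directions, and the difference between them was tested directly. The median log2 difference between MSN500 and Stober50 was 1.04, higher in MSN500 in 26 of 26 genes (camera adjusted p = 1.29e-24, adjusted p = 0.00668 with an estimated correlation). Removing the length and GC content trend left at least 99.0% of either list mean, and leaving out any 1 of the 9 libraries left at least 89.1%, which argued against that trend and against a single library as the whole cause. Among the particles the list mean followed the labelled dosage, with log2 differences from control of -0.28 ± 0.0411 at 13.1 µg/ml, 0.01 ± 0.0186 at 16.8, 0.39 ± 0.0439 at 84 and 0.66 ± 0.0134 at 111.8 (SD, n = 3). A response in 1 direction from control would not place Stober50 below control, where it lay (camera adjusted p = 0.0128 with an estimated correlation). That value is part of the pattern itself, so it is no independent test of such a response. A biological difference between the particles is a hypothesis that may account for the pattern, but an effect of dosage among the particles stays open, since particle type, size and dosage changed together and their parts were not separated.

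In the authors' deposited exon table, which entered no test of genes or lists, 160 genes had an exon with a score of at least 20 and an absolute log2 ratio of at least 1 between MSN-PEG500 and MSN500. Counts were 141, 280 and 140 between MSN-PEG500 and control, Stober50 and Stober500, and 2 to 27 for pairs of groups without MSN-PEG500. In each pair with MSN-PEG500, exons lower in MSN-PEG500 had a median position of 0.00623 to 0.00662 of the gene's span from its start. Exons higher in MSN-PEG500 had medians of 0.235 to 0.769. The counts therefore cannot be read as a change of exon use alone. Replicates were not modelled in that table.

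Of 35 oxidative phosphorylation genes, 11 were lower in MSN-PEG500 than in MSN500 (camera adjusted p = 3.76e-08, adjusted p = 0.283 with an estimated correlation), and short genes tended to be lower. Relative to control the list mean was -0.02 ± 0.0370 in MSN-PEG500 (SD, n = 3; camera adjusted p = 0.639). It was 0.08 ± 0.0196 in MSN500 (camera adjusted p = 0.00816), 0.06 ± 0.0252 in Stober50 and 0.06 ± 0.0199 in Stober500. Against control, rho with exonic length was 0.0304 for MSN-PEG500 and -0.111 for MSN500. The list and length differences therefore cannot be read as a lowering by MSN-PEG500 from control. Removing the length and GC content trend left 74.9% of the oxidative phosphorylation list mean (from -0.10 ± 0.0799 to -0.07 ± 0.0623, SD over 35 genes; camera adjusted p = 3.23e-04 after, with the preset correlation), which argued against that trend as the whole cause for the list; for short genes in general the test is void, because the removal takes out the trend itself. Over the 160 genes of the exon table, exon log2 ratio and exon position along the gene had Spearman's rho 0.185 (genes are not independent replicates). Exons higher in MSN500 lay at a median of 0.00623 of the gene's span from its start, and those higher in MSN-PEG500 at 0.769. A difference in RNA integrity or end bias of the MSN-PEG500 libraries, or of a single library among them, may therefore contribute and stays open. The exon table did not model replicates, so it cannot tell these apart. Without MSN-PEG500 replicate 3, the library that stood apart, fold change and exonic length still had rho 0.198 (0.267 with all libraries). This argued against that library as the whole cause of the length relation. The relation to GC content moved from rho -0.219 to -0.0262 without that library, so it rested largely on it. Whether the exon values also rest on that library or on GC content was not tested. An effect of pegylation or of dosage was not tested separately.

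MSN500 changed 5489 genes against control and Stober500 changed 1. Thinning every library to the lowest total left 5239 genes for MSN500, which argued against depth. Leaving out a Stober500 library raised its count to as many as 90 (without Stober500 replicate 3), under the bound of 100 set beforehand but in the direction that a larger spread predicts. Without that library rho of log2 changes and GC content also moved, from 0.0182 to 0.162. Its part in the count of 90 was not tested. Lysosome genes lay at a mean log2 difference from control of 0.05 ± 0.0187 in Stober500 and 0.72 ± 0.0171 in MSN500 (SD, n = 3). For that list, this argued against a larger spread between the Stober500 libraries as the whole cause. Replicate pairs differed by a chi-square of 2.445 to 6.81 per degree of freedom in Stober500 and 2.19 to 6.40 in MSN-PEG500. With such a spread MSN-PEG500 still changed 4397 genes against control. This argued against spread as the whole cause of the gap in counts. Whether spread hid some changes with Stober500 stays open. The labelled dosages differed by a ratio of 6.65, so particle and dosage cannot be told apart for these 2 groups. No comparison at a single dosage was analysed here.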

How the results depend on the processing

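The removal of the length and GC content trend and the list tests without single libraries were chosen only after the results were seen. Of 6197 values of named genes under the alternatives, 5921 kept their side of the threshold, 267 lost the call and 9 gained one. Among values called in the main fit or in the alternative, 0 reversed direction. Direction was not compared for values called in neither. For changed genes with MSN500 against control, the counts were 4824 to 5167 without single libraries, and for MSN-PEG500 3723 to 4246.

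A stricter threshold, which takes fewer genes by construction, left 6 genes for Stober50, 0 for Stober500, 394 for MSN500 and 297 for MSN-PEG500 against control, 0 for Stober50 and 351 for MSN500 against Stober500, and 3 for MSN-PEG500 against MSN500. At an unadjusted p under 0.05, which a share of 0.05 of unchanged genes would pass, edgeR gave 1526 of 12798 genes for Stober500 against control. It gave 1795 for Stober50 against Stober500. The single gene of Stober500 against control became 3 with upper quartile factors, 91 with DESeq2, 4 with limma-voom, 22 with the length and GC content trend removed and 2 with only the groups compared; the cause was not tested. With an estimated correlation 14 gene list tests passed in place of 70. Without single libraries 62 to 77 passed. Fry passed 68 tests, which held 50 of the 70. In Stober500 against control fry gave an adjusted p = 0.119 for lysosome, 0.125 for oxidative phosphorylation and 0.581 for glycolysis genes. Of the 70 calls, 55 stayed without all libraries of replicate number 3 and 65 with the length and GC content trend removed.

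Without single libraries, Stober50 against control gave 412 to 892 genes (533 without Stober50 replicate 1, 412 without Stober50 replicate 2, 584 without control replicate 1, 631 without control replicate 2). Stober500 against control gave 0 to 90 (0 without Stober500 replicate 1, 2 without replicate 2, 90 without replicate 3, and 6, 2 and 2 without control replicates 1, 2 and 3). Stober50 against Stober500 gave 144 to 302 (158 and 186 without Stober50 replicates 2 and 3, 176 and 144 without Stober500 replicates 1 and 2). MSN-PEG500 against MSN500 gave 420 to 1032 (420, 651 and 606 without MSN500 replicates 1, 2 and 3, 615 without MSN-PEG500 replicate 3). The cause was not tested.

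The genes that differ among the 5 groups were selected on the same differences, so a correlation over them is no independent check. Over only these genes the correlation of effects moved to 0.591 (Stober50 and Stober500), 0.571 (Stober50 and MSN500), 0.547 (Stober50 and MSN-PEG500), 0.260 (Stober500 and MSN-PEG500) and 0.935 (MSN500 and MSN-PEG500). With the stricter filter it was 0.263 for Stober500 and MSN500, 0.252 for Stober500 and MSN-PEG500 and 0.913 for MSN500 and MSN-PEG500. Without single control libraries, which raises shared noise by construction, ranges were 0.632 to 0.676, 0.538 to 0.576, 0.518 to 0.559, 0.347 to 0.399, 0.353 to 0.407 and 0.881 to 0.889, for Stober50 with Stober500, MSN500 and MSN-PEG500, Stober500 with MSN500 and MSN-PEG500, and MSN500 with MSN-PEG500.

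With the replicate number as a block, the comparisons with control gave 1151 (Stober50), 9 (Stober500), 5633 (MSN500) and 4546 (MSN-PEG500) genes. Over 30 pairs of libraries with the same number, deviations from group means correlated at -0.164 to 0.109, and 7 of 15 libraries correlated best with their own number, so the numbers were not taken to pair the samples.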

Other observations

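None of the gene lists was chosen after the results were seen, and the splits of the samples were fixed beforehand, while leaving single libraries out of the list tests was chosen after.

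Both mesoporous particles moved genes of osteoclast-like differentiation in both directions, 8 of 13 up and 4 down with each (the same adjusted over the list alone). Ctsk, the osteoclast protease cathepsin K, rose by 1.68 ± 0.09 on the log2 scale with MSN500 and by 1.68 ± 0.09 with MSN-PEG500 (SE, n = 3 per group), while Tnfrsf11a, the receptor RANK, fell by 0.90 ± 0.04 with MSN500. The list had a camera adjusted p = 0.0665 with MSN500 (0.0447 without MSN500 replicate 1) and adjusted p = 0.0229 with MSN-PEG500 (0.0508 without control replicate 1, and adjusted p = 0.346 with an estimated correlation). Of 10 dendritic cell markers, 3 rose and 1 fell with MSN500 (camera adjusted p = 0.153), with the costimulatory gene Cd86 at 1.25 ± 0.12 and the integrin gene Itgax at 0.98 ± 0.11. Of 22 matrix protease and remodelling genes, 14 rose and 5 fell with MSN500 (14 and 7 adjusted over the list alone; camera adjusted p = 0.0257, adjusted p = 0.381 with an estimated correlation).

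Several other lists did not pass with MSN500. Apoptosis genes rose in 8 and fell in 11 of 25 cases (camera adjusted p = 0.777), with the antiapoptotic gene Bcl2l1 at 1.30 ± 0.06. Immediate early genes rose in 7 and fell in 7 of 25 cases (adjusted p = 0.993), with Gadd45b at 1.68 ± 0.10 and Klf4 at -0.93 ± 0.10; their median (0.11) and mean (0.03) were above 0 and the test direction was down. Scavenger receptor genes rose in 11 and fell in 12 of 29 cases (adjusted p = 0.700), with the lipoprotein receptor gene Olr1 at -1.51 ± 0.13. ATF4 genes rose in 10 and fell in 7 of 27 cases (adjusted p = 0.695), heat shock genes rose in 7 and fell in 3 of 16 (adjusted p = 0.269), and alternative activation genes rose in 5 and fell in 4 of 13 (adjusted p = 0.695). LXR targets rose in 3 and fell in 6 of 14 cases (adjusted p = 0.993), with a median of 0.04, a mean of -0.04 and an upward test. Replication-dependent histones rose in 2 and fell in 0 of 7 cases, with a median of -0.22, and mitochondrially encoded genes rose in 0 and fell in 0 of 7 (each adjusted p = 0.993). With MSN-PEG500, scavenger receptor genes had a median of -0.03, a mean of 0.05 and an upward test (adjusted p = 0.772). Median, mean and test direction also differed in sign for other lists, none of which passed. These were the alternative activation, heat shock, apoptosis and mitochondrially encoded lists with Stober50, the NF-kB, histone, apoptosis, metal, inflammasome and mitochondrially encoded lists with Stober500 and the mitochondrially encoded list with MSN500. Between particles they were the alternative activation, glycolysis and mitochondrially encoded lists (Stober50 against Stober500), the LXR, alternative activation, histone, glycolysis and mitochondrially encoded lists (MSN500 against Stober500) and the mitosis, heat shock, ER chaperone and dendritic cell lists (MSN-PEG500 against MSN500).

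The 6 libraries of any pair of groups have 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 969 and 2 for Stober50, 5489 and 0 for MSN500, and 4397 and 0 for MSN-PEG500 against control, and 287 and 4 for Stober50 and 5045 and 1 for MSN500 against Stober500, with 1027 and 0 for MSN-PEG500 against MSN500. In each of these 1 split, the real one, gave as many genes. For Stober500 against control the real count was 1, 4 of 10 splits gave as many, and the highest other split gave 29, which points to a structure of these samples whose source was not tested. The relation of log2 changes to GC content in this comparison depended on single libraries. Its rho was 0.162 without Stober500 replicate 3 and -0.132 without control replicate 1. For the test among all 5 groups, 1 of 30 splits, the real one with 6364 genes, gave as many and the highest other gave 0. This argued against a random grouping of these libraries, with 1 of 30 the smallest share that so few splits allow. Random splits mix the mesoporous libraries with the others, which widens the spread within groups, so low counts in them were likely. They do not address batches, which the labels do not name.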
